A study of Mus musculus with 20 samples.

How the data were processed

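The deposited tables hold raw UMI counts per gene and cell for 27174 CD45-sorted tumour cells, 25242 ST2-sorted node cells and 35369 ST2-sorted tumour cells. The authors deposited counts (whole numbers, not normalized), already filtered for cells by settings that were not stated. Total counts and genes per cell as deposited were checked and equalled the sums of the tables in every cell. Per the file headers, percent values of mitochondrial counts were given for each cell; in both ST2-sorted tables the deposited percent was 0 in every cell although 13 mitochondrial genes had counts, so it was recomputed. The submitters' processing notes name Cell Ranger 7.0.0, Seurat 5.0.0 and the mm10 genome build. The other deposited columns (class labels, batch, library names) are annotations in text form, per the file headers.

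Cells were assigned to libraries by the deposited library names. Names with B2, whose treated libraries are marked 7d, were matched to the Tx7 arm. Names with B1, whose treated libraries are marked 3d, were matched to the Tx1 arm by elimination, a match the labels do not state. Batch and arm therefore coincide and cannot be told apart; treatment and genotype were compared within an arm. The deposited class labels were used as given. The leading genes of several classes belong to another cell type than the label names. Among their 50 leading genes, the node class labelled Cd4 held 3 of 10 ILC2 markers and at most 1 marker of any other type, and the node class labelled Cd8 held 2 NK and 2 CD8 T cell markers. The node class labelled Cd8 cycling held 4 NK and 2 CD8 T cell markers, and the CD45 class labelled Macrophage 4 monocyte and 4 macrophage markers. These classes are named here by label only, with no cell type read from it, and classes with a larger mismatch entered the share tests and their correction but are not reported by name, apart from the CD45 class labelled ILC3 (7 of 7 migratory dendritic cell markers). The Treg1 class had a median of 1951 UMIs per cell in the node, where 53.1% of its cells had over 10% mitochondrial counts, and is called by its label only.

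Counts were summed per library and class. The lead classes, chosen before the data were examined, were regulatory T, ILC2, CD8 T and other CD4 T cells, each fitted where it had 20 cells or more in every library; other classes, such as dendritic cells, were not fitted. The classes fitted were Treg, Treg1, Cd4 and Cd8 in the node and Treg and Treg1 in the tumour, with the whole sort. Sums were tested with edgeR 4.0.16 in R 4.3.3 (TMM, filterByExpr, quasi-likelihood F test, Benjamini-Hochberg threshold 0.05). The SE given for a gene is its absolute log2 fold change over the square root of F, not a fitted standard error of the coefficient. Genotype, Tx1, Tx7 and their difference came from a model of the conditions plus genotype with 3 residual degrees of freedom. The interaction of genotype and treatment had 2, and tissue had 7. In the interaction model of node Treg cells edgeR estimated no spread of the variances between genes around their trend. Each gene there was tested against the trend and not its own spread between libraries, so p can be extreme. The tumour Treg interaction fit gave weight to each gene's own spread (6.715 prior degrees of freedom). The counts of these fits are therefore not on equal terms. Gene lists (17, fixed before the data were examined) were tested with camera at a preset correlation of 0.01, with limma 3.58.1, with an estimated correlation and with fry as alternatives. Cell shares were compared by exact two-sided permutation of mean logit shares (70 arrangements, smallest p 0.0286, which do not keep arm and treatment fixed). CD45-sorted libraries were given as values with exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only.

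Genes were named by a rule fixed before the data were examined. For tested contrasts, genes past the threshold with the same sign in every pair were ranked by fold change, and the first 12 each way were taken. From each list, the members past the threshold with the same sign in every pair and the largest changes were taken. Where none qualified, the members with the smallest p were taken, whatever their sign in single pairs. The demand of a common sign for list members was not part of the rule as fixed. For CD45-sorted libraries, genes with 50 CPM (counts scaled to the library total) in at least 1 library and a log2 ratio of at least 1 in size and of the same sign in both pairs were ranked by the smaller size, and the first 10 each way were taken. Ribosomal, mitochondrial, receptor segment, haemoglobin, Xist, Y-linked genes and gene models named Gm or ending in Rik were left out of the ranking. A gene named outside this rule is marked as named after its values were seen.

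Alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, doublets left out (Scrublet as implemented in scanpy 1.11.5) and each library left out in turn. Because the automatic Scrublet threshold marked few cells, cells with the highest scores were also left out (a share rising with the number of cells in a library), an alternative chosen after seeing the data. So were leaving out cells with over 10% mitochondrial counts, the cycling Treg subset, or both MSM-IL33ko libraries of the Tx1 arm, and thinning counts to the smallest library. Tested on simulated data, the node Treg interaction recovered part of 2-fold changes and nearly all 4-fold changes, at 46% and 98%. Of the calls on simulated data, 5.88% were false for that interaction, 16.9% for node Treg Tx7 and 22.4% for the tumour Treg interaction. These lie above the nominal 5%, so counts can hold more false calls than nominal. Simulated genes were drawn independently, with the dispersions of the same fits. Shifts shared by genes were not simulated, so these rates need not hold for the real libraries. Where a library left out leaves a condition with 1 library, that library is assumed to vary like the others for treatment contrasts. For genotype and the interaction the model fits it exactly, so it adds nothing to the estimate. Leaving out 1 library then removes its matched pair of genotypes, and a changed count cannot be assigned to either library of that pair.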

Results

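Single-cell RNA sequencing was performed on 20 libraries from tumour-bearing mice of the genotypes MSM-IL33wt and MSM-IL33ko. The labels do not spell out MSM; per the series title the study concerns IL-33, an alarmin cytokine, made by lymph node macrophages, and ko is read here as its loss. Of these, 16 libraries held cells sorted for ST2, the IL-33 receptor encoded by Il1rl1, from the tumour-draining lymph node (TDLN, 8 libraries) or the tumour (8 libraries). The other 4 held CD45-sorted tumour cells. PLX4720 is an inhibitor of mutant BRAF. The ST2-sorted libraries came from an arm with 1 treatment (Tx1) and an arm with 7 treatments (Tx7), each with its own untreated library for either genotype. Every combination of sort, tissue, genotype, arm and treatment had 1 library, so no combination was replicated. Libraries held 551 to 8835 cells and 5492735 to 92640093 UMIs.

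The first question was whether the response of ST2-sorted lymph node cells to PLX4720 depended on macrophage IL-33. In the class annotated as regulatory T cells (Treg), the treatment effect differed between the genotypes for 1258 of 13632 genes, with 421 higher and 837 lower in MSM-IL33ko relative to MSM-IL33wt (edgeR quasi-likelihood test, interaction term, 8 libraries). Of these, 1230 had the same sign in both arms, which is no separate replication, as the test favours genes whose arms agree. Genes of cell division carried part of this difference: 14 of 16 measured members of the proliferation list fell, 15 when adjusted over the list alone, with a median log2 difference of -1.50. All 16 were negative in the Tx1 arm (median -1.61) and in the Tx7 arm (median -1.06). The list passed camera with its preset correlation (adjusted p = 1.2e-11), and its adjusted p = 0.903 with an estimated correlation. Library size followed the pattern of the interaction in the Tx1 arm. Treated MSM-IL33wt held 6051 cells and untreated MSM-IL33ko 1773, against 592 in treated MSM-IL33ko and 551 in untreated MSM-IL33wt. In the Tx7 arm these were, in the same order, 3107, 5317, 4475 and 3376. Cell number was not tested as a source, and thinning counts does not equalize it.

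Cytotoxic genes formed the second group, and Xcl1 and Gzma among them were also leading genes of the node class labelled Cd8 cycling. Of 17 measured members of the cytotoxic effector list, 10 fell, 12 when adjusted over the list alone, with a median log2 difference of -2.23 (camera adjusted p = 5.0e-08, adjusted p = 0.903 with an estimated correlation). Among the largest negative differences were those of Xcl1, a chemokine that attracts dendritic cells (log2 difference -7.63 ± 0.67 SE, adjusted p = 3.2e-26), Ifitm1 (-6.21 ± 0.61 SE), Ccl4 (-5.20 ± 0.32 SE), Klrd1 (-4.92 ± 0.88 SE) and the granzyme gene Gzma (-4.27 ± 0.41 SE). In the other direction, the type 2 cytokine gene Il4 had a log2 difference of 4.51 ± 0.74 (SE, adjusted p = 1.5e-07). Of 14 immediate early and dissociation stress genes, a quality list, 7 rose, and of 17 type I interferon response genes, 5 rose. Neither list passed camera (adjusted p = 0.0704 and 0.328). In the Tx1 arm all 14 genes of the quality list had positive differences (median log2 1.73), and in the Tx7 arm 9 of 14 (median 0.33). Of the other lists, naive and memory T genes had 3 that rose and 1 that fell, checkpoint genes 1 and 2, type 2 cytokine genes 1 and 2, and inflammatory myeloid genes 0 and 2. The lists of Treg core, tissue and effector Treg, ILC2 identity, interferon-gamma, NF-kB, T cell receptor activation, TGF-beta, mitochondrially encoded and macrophage genes had at most 1 gene each way, and none of these 13 lists passed camera. Fitted values of genes with no counts in some libraries depend on the prior count and are no bounds, and the SE taken from them share this limit. The p values of these genes rest on the variance trend, not on each gene's own spread between libraries.

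**Figure D1:**
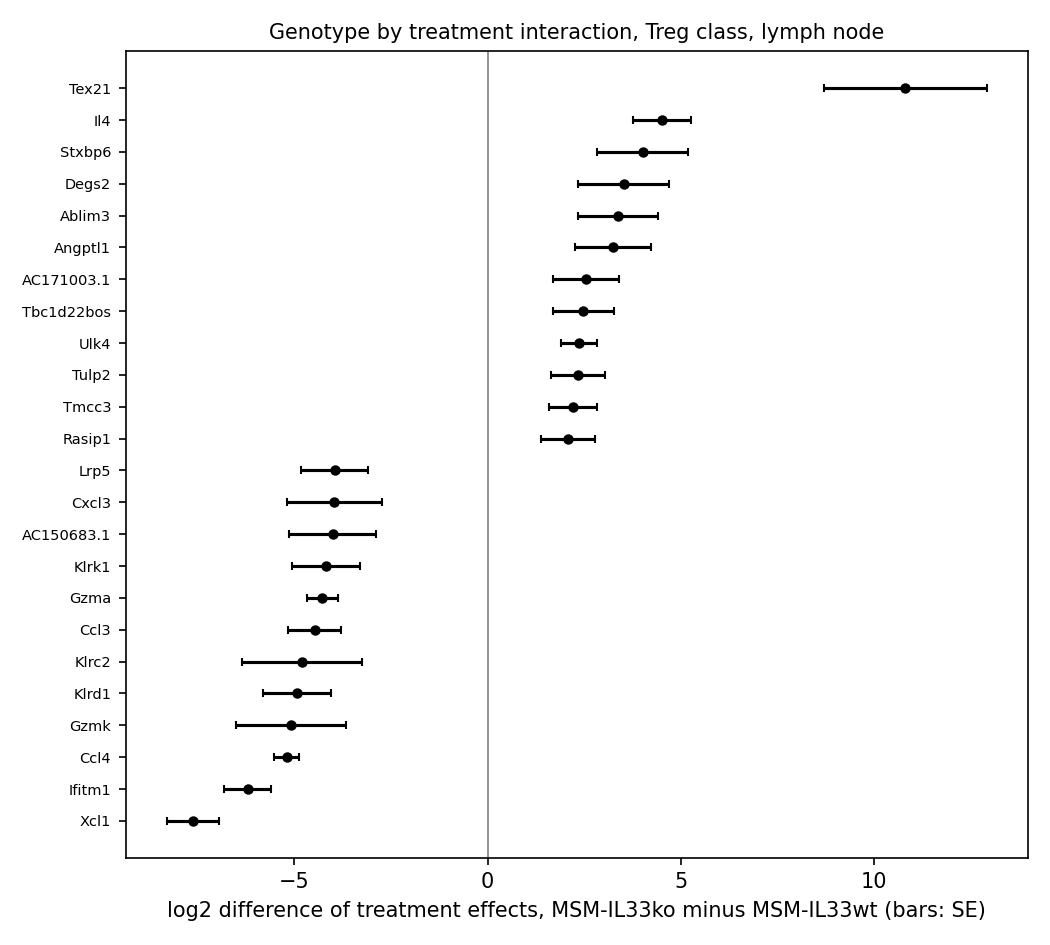
Log2 difference of the PLX4720 effect between genotypes (x axis, MSM-IL33ko minus MSM-IL33wt) for the genes named by rule (y axis) in Treg-class cells of the lymph node. Points are fitted values over 8 libraries and bars are SE computed from the F statistic. Xcl1 lies lowest at -7.63.

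The deposited annotation divides Treg cells into subsets, of which 1 is named as cycling. In MSM-IL33wt nodes this subset made up 13.6% of annotated Treg cells in the untreated and 27.9% in the treated library of the Tx1 arm, and 15.0% and 28.0% in the Tx7 arm. In MSM-IL33ko nodes it made up 32.5% untreated and 15.0% treated in the Tx1 arm, and 23.6% and 20.3% in the Tx7 arm. The difference between the treatment effects, a test chosen after the shares were seen, had an exact permutation p = 0.0286 (two-sided, 70 arrangements, the smallest p these allow) and an adjusted p = 0.114 over 4 subsets. Another deposited class, labelled Cd8 cycling, made up 4.25% and 9.14% of cells in the treated MSM-IL33wt nodes of the Tx1 and Tx7 arms and 4.91% in the untreated MSM-IL33ko node of the Tx1 arm, against 0.0940% to 0.907% in the other 5.

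The count of interaction genes depended on the matched pairs of genotypes, which leaving out 1 library takes out of the estimate. With the cycling subset left out it was 244, and DESeq2 called 557. In the Tx1 arm it was 555 without treated MSM-IL33ko, 386 without untreated MSM-IL33ko, 559 without treated MSM-IL33wt and 390 without untreated MSM-IL33wt. In the Tx7 arm it was 369 without treated MSM-IL33ko and 359 without treated MSM-IL33wt, and 1673 and 1668 without the untreated libraries of the respective genotype. In the whole node sort no gene passed for the interaction in edgeR (1694 at an unadjusted p under 0.05, DESeq2 186). There, 303 genes passed without the low-count filter. Leaving out 1 library of the Tx7 arm gave 378 (untreated MSM-IL33ko), 431 (untreated MSM-IL33wt) and 2 (treated MSM-IL33wt), and leaving out 1 of the Tx1 arm gave 54 (untreated MSM-IL33ko) and 58 (untreated MSM-IL33wt).

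**Figure D2:**
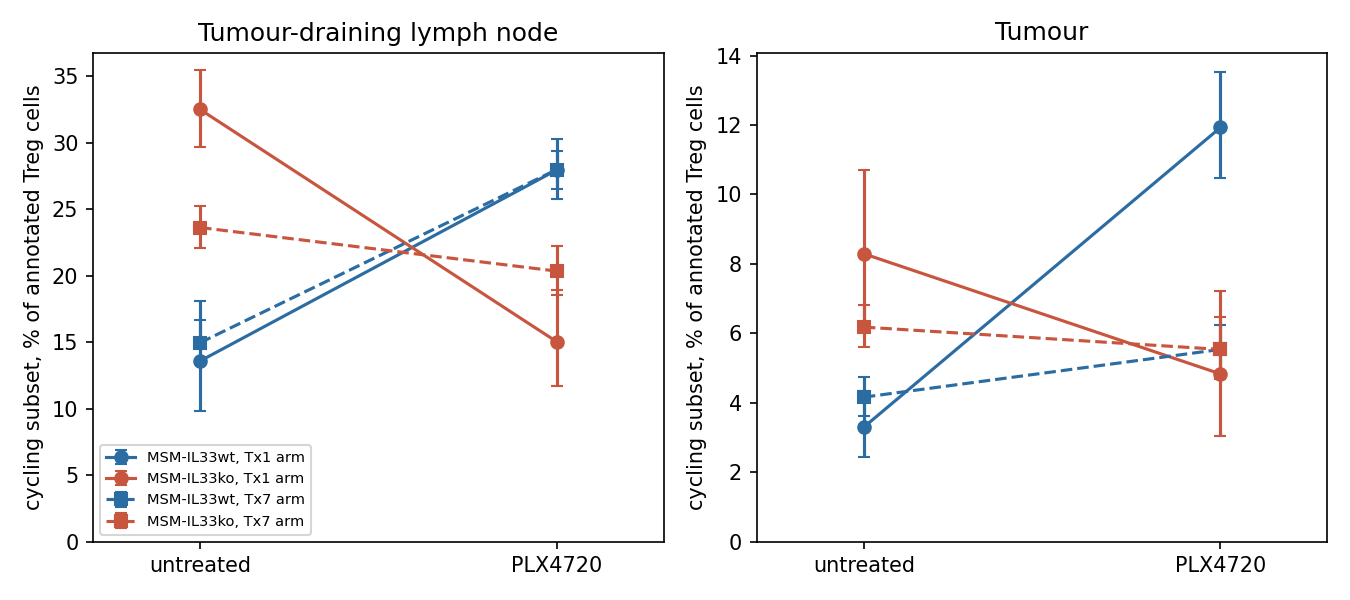
Share of the cycling subset among annotated Treg cells (y axis, percent) without and with PLX4720 (x axis) in node and tumour, 1 point per library, with bars showing exact 95% intervals. In the node the MSM-IL33wt lines go from 13.6% to 27.9% and from 15.0% to 28.0%, and both MSM-IL33ko lines go down.

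Few genes passed for differences common to both genotypes or to all conditions in node Treg cells. The model for these had no interaction term, so the interaction added to its residual spread (biological coefficient of variation 0.178, against 0.121 with that term). By chance, 681.6 of 13632 genes would have an unadjusted p under 0.05, more than any contrast below gave. Few passing genes therefore do not show that few such differences exist. For genotype, 2 genes passed, the Y-linked genes Ddx3y and Eif2s3y, named here after their values were seen; 254 genes had an unadjusted p under 0.05, and DESeq2 called 1 gene. The count was 0 without either treated library of the Tx1 arm, 6 without the untreated MSM-IL33ko library of the Tx7 arm and 4 without the untreated MSM-IL33wt library of either arm. No gene passed in edgeR for Tx1 (206 at an unadjusted p under 0.05, DESeq2 0). None passed for Tx7 (412 unadjusted), where DESeq2 called 11 genes and leaving out both MSM-IL33ko libraries of the Tx1 arm gave 57. Leaving out either untreated library of the Tx1 arm gave 12 genes for Tx7, and leaving out the untreated MSM-IL33ko or MSM-IL33wt library of the Tx7 arm gave 5 and 1. None passed in edgeR for the difference between Tx7 and Tx1 (269 unadjusted, DESeq2 0). For Tx7, the type I interferon response list (16 of 17 positive, median log2 0.42) and the NF-kB list (13 of 14 positive, median 0.25) passed camera, with adjusted p = 0.859 and 0.499 with an estimated correlation.

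In the node class labelled Cd8, 23 genes passed for Tx7, 22 of them higher after treatment in both genotypes. They included Penk (log2 fold change 3.74 ± 0.71 SE), Apoe (3.10 ± 0.54 SE), the checkpoint gene Lag3 (2.05 ± 0.46 SE) and the IL-12 receptor gene Il12rb2 (1.88 ± 0.35 SE). The chemokine gene Ccl4 fell by 1.91 ± 0.39 (SE) on the log2 scale. Without the low-count filter, 48 genes passed for Tx7 in this class. No gene passed with counts thinned to the smallest library, DESeq2 called 1, and 81 passed without both MSM-IL33ko libraries of the Tx1 arm. Leaving out 1 library of the Tx1 arm gave 44 (treated MSM-IL33ko), 39 (treated MSM-IL33wt) and 62 (either untreated library), and leaving out 1 of the Tx7 arm gave 39 (treated MSM-IL33ko) and 12 (untreated MSM-IL33ko).

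Other counts in the node classes labelled Cd4 and Cd8 depended on the libraries and settings used. In the Cd4 class 4 genes passed for Tx7, all higher, namely Spp1, Pak1, Dgat1 and Cblb, with 0 in thinned counts, 3 with DESeq2 and 2 to 100 leaving out 1 library (100 without treated MSM-IL33ko of the Tx7 arm). This count was 140 without the low-count filter and 185 without both MSM-IL33ko libraries of the Tx1 arm. For genotype, 2 genes passed in the Cd4 class (1 to 13 leaving out 1 library; Apoe higher in 4 of 4 pairs and Xcl1 lower in MSM-IL33ko, though higher in 1 of 4 pairs) and 3 in the Cd8 class (14 to 44 leaving out any 1 library, 0 in thinned counts), namely Gm42726 and Olfr1369-ps1, both named after their values were seen, and Ccl4, which fell by 2.31 ± 0.38 (SE) on the log2 scale. Of these 3, 2 had the same sign in every pair, all but Olfr1369-ps1. For genotype DESeq2 called 2 genes in the Cd4 class and 1 in the Cd8 class, none of them lower, so the lower Xcl1 and Ccl4 were not called. The genotype counts were 69 (Cd4) and 31 (Cd8) without the low-count filter, and 105 and 74 without both MSM-IL33ko libraries of the Tx1 arm. For Tx1, 2 genes passed in the Cd8 class, Olfr1369-ps1 and, with opposite signs in the genotypes and named after its values were seen, S100a4 (9 to 17 leaving out any 1 library, 0 in thinned counts and with DESeq2, 14 without the low-count filter).

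The next question was which of these differences occurred in the tumour. No gene of tumour Treg cells passed in edgeR for genotype (282 at an unadjusted p under 0.05, DESeq2 1), Tx1 (789 unadjusted, DESeq2 4), Tx7 (1020 unadjusted, DESeq2 95) or the interaction (409 unadjusted, DESeq2 2). By chance, 705.4 of 14108 genes would have an unadjusted p under 0.05, more than genotype and the interaction gave. The lack of passing genes there does not show that no differences exist. The interactions of node and tumour were not compared by a test. Leaving out any 1 library gave 8 to 142 interaction genes, and 69 genes for Tx1 and 88 for Tx7 passed without the treated MSM-IL33ko library of the Tx1 arm. Without the treated MSM-IL33wt library of that arm, 6 passed for Tx1 and 78 for Tx7, and 28 for genotype, against 22 for genotype without treated MSM-IL33ko. Leaving out either untreated library of the Tx7 arm gave 2 genes for genotype and 2 for Tx7. For Tx7, all 17 measured type I interferon response genes had positive values with a median log2 of 0.92, and 15 passed when adjusted over the list alone (camera adjusted p = 2.0e-16, adjusted p = 0.352 with an estimated correlation). Macrophage genes moved with them: 12 of 14 had positive values, with a median log2 of 1.52 (camera adjusted p = 0.000903, adjusted p = 0.352 with an estimated correlation). Without the MSM-IL33ko libraries of the Tx1 arm, 677 genes passed for Tx7. All 16 proliferation genes had negative interaction values in the tumour (median -1.06), from medians of -2.09 in the Tx1 arm and -0.0077 in the Tx7 arm (camera adjusted p = 1.3e-05, adjusted p = 0.864 with an estimated correlation).

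A second class, labelled Treg1, held cells with fewer UMIs (a median of 2827 against 8657 in tumour Treg cells). In it, 92 genes rose and 1 fell in MSM-IL33ko tumours. Among the leading ones were H2-M2 (log2 fold change 3.32 ± 0.65 SE), Ifi205 (3.22 ± 0.36 SE), Cfb (2.77 ± 0.40 SE), a complement component, and Cxcl9 (2.49 ± 0.34 SE), an interferon-induced chemokine. The count of 93 was 16 with counts thinned to the smallest library, 53 with DESeq2, 59 without the highest Scrublet scores, 225 without the low-count filter and 165 without both MSM-IL33ko libraries of the Tx1 arm. It was 11 and 15 without the treated MSM-IL33ko and MSM-IL33wt libraries of the Tx7 arm, 173 and 166 without those of the Tx1 arm, and 59 without untreated MSM-IL33ko of the Tx7 arm. For Tx7, 36 rose and 3 fell, led by the monocyte-attracting chemokine genes Ccl8 (4.17 ± 0.49 SE) and Ccl12 (3.82 ± 0.45 SE). This count of 39 was 1 with thinned counts, 17 with DESeq2, 194 without the low-count filter and 263 without both MSM-IL33ko libraries of the Tx1 arm. Leaving out 1 library of the Tx7 arm gave 2 (treated MSM-IL33ko), 1 (untreated MSM-IL33ko) and 10 (untreated MSM-IL33wt), and leaving out any 1 of the Tx1 arm gave 84 to 95. The share of the moMacrophages class did not pass the correction between genotypes in the tumour; in MSM-IL33ko it was 13.8% ± 10.1 (SD, n = 4) of cells against 3.67% ± 2.36 (SD, n = 4), higher in 4 of 4 pairs (exact permutation p = 0.0286, adjusted p = 0.286 over 10 classes). Treg cells made up 61.7% ± 11.1 (SD, n = 4) against 71.9% ± 6.08 (SD, n = 4), lower in 4 of 4 pairs (exact permutation p = 0.143, adjusted p = 0.571). With labels permuted within matched pairs the permutation p = 0.125, the smallest that 4 pairs allow. In the node the moMacrophages share went the other way between genotypes. It was 1.71% ± 0.971 (SD, n = 4) in MSM-IL33ko against 4.08% ± 1.86 (SD, n = 4) in MSM-IL33wt, lower in 4 of 4 pairs (exact permutation p = 0.0857, adjusted p = 0.857). With treatment, the tumour moMacrophages share was higher in 4 of 4 pairs, at 12.1% ± 11.5 (SD, n = 4) against 5.39% ± 3.67 (exact permutation p = 0.4, adjusted p = 0.735). RNA from macrophages was not tested as a source of the Treg1 genes that rose for Tx7. No class passed the correction for genotype or treatment in either tissue. Even at the smallest permutation p possible, 0.0286, 1 class alone could not pass over 10 classes (adjusted p = 0.286). The lack of passing classes therefore does not show that shares were alike.

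Tissue gave the highest count of genes among the contrasts tested. Between tumour and node Treg cells, 4886 genes were higher in the tumour and 3508 lower, of 14655 tested over 16 libraries. All 17 type I interferon response genes rose (median log2 2.67) and all 16 proliferation genes fell (median -1.65). All 9 measured type 2 cytokine genes rose, and 15 of 17 cytotoxic genes rose. With an estimated correlation, each of these lists had an adjusted p = 0.164 or 0.182. Leading genes were those of other cell types: the neutrophil genes S100a9 and S100a8 (8.60 ± 0.37 SE) and the macrophage gene C1qb (7.24 ± 0.31 SE) were higher in the tumour, and the B-lineage gene Ighg1 (-12.03 ± 0.35 SE) was lower. The genotype effect did not differ detectably by tissue in Treg cells (0 genes in edgeR, 207 at an unadjusted p under 0.05, DESeq2 0). By chance 732.75 genes would have such an unadjusted p, so the lack of passing genes does not show that no difference exists.

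CD45-sorted tumour cells were compared as values only. Cells of the class labelled Macrophage were a larger share with PLX4720 in both genotypes, from 6.22% (exact 95% interval 5.61% to 6.88%) to 9.07% (8.37% to 9.81%) in MSM-IL33wt and from 11.3% (10.6% to 12.1%) to 16.05% (15.2% to 16.9%) in MSM-IL33ko tumours, and a larger share in MSM-IL33ko tumours with and without treatment, by less than the 1 log2 unit of the size rule. The 1 class past that rule between genotypes, labelled ILC3 and 2.40 (PLX4720) and 2.34 (untreated) times as high in MSM-IL33ko, had the leading genes of migratory dendritic cells. CD8_effector cells were a smaller share with PLX4720, from 19.6% to 9.69% in MSM-IL33wt and from 15.0% to 8.14% in MSM-IL33ko. NK cells were a larger share, from 13.6% to 17.0% and from 11.1% to 15.5%. TReg_NLTlike.NLT.Effector cells went from 6.86% to 10.7% in MSM-IL33wt and from 6.49% to 5.85% in MSM-IL33ko tumours.

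**Figure D3:**
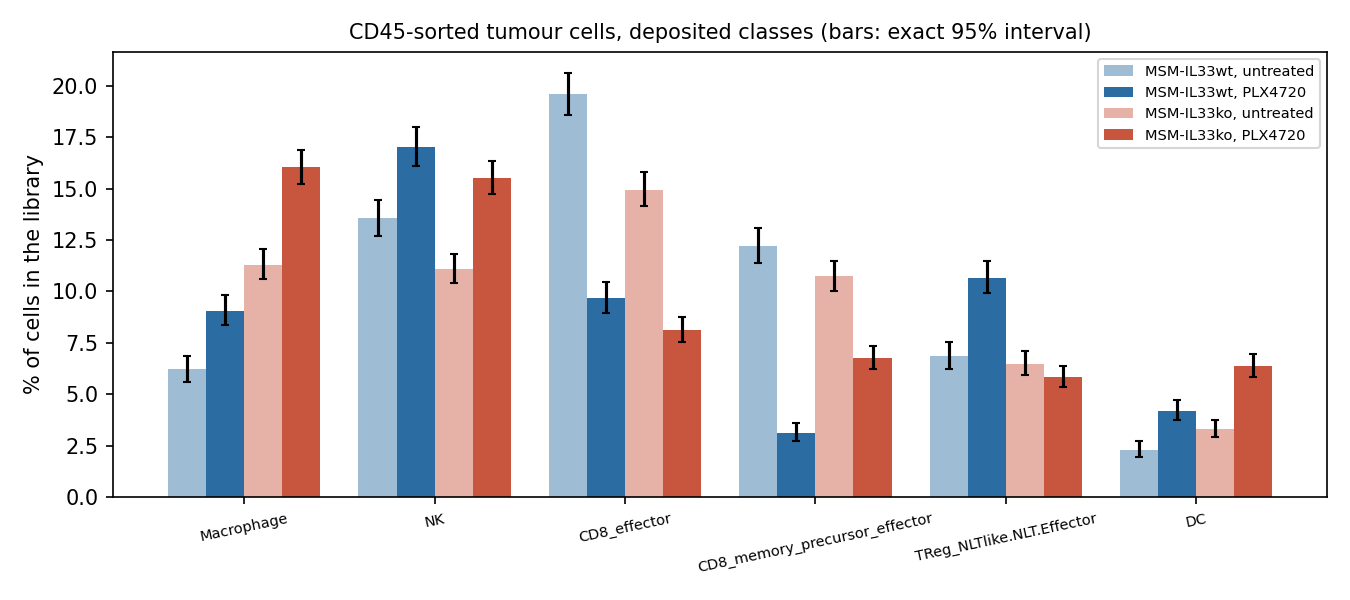
Percent of cells (y axis) in 6 deposited classes (x axis) of the 4 CD45-sorted tumour libraries, with bars showing exact 95% intervals. Macrophage shares run from 6.22% in untreated MSM-IL33wt to 16.05% in treated MSM-IL33ko.

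In the whole CD45 sort, 24 genes were at least 1 log2 unit higher and 1 lower with PLX4720 in both genotypes. They included the chemokine gene Ccl2 (log2 ratio 2.13 in MSM-IL33ko and 2.44 in MSM-IL33wt) and the sterol pathway genes Fdps, Cyp51 and Insig1, with ratios from 1.27 to 1.98. Of the 14 immediate early and dissociation stress genes, a quality list, 13 were higher with PLX4720 in both genotypes (median log2 0.36). In the class labelled Macrophage, the sterol pathway genes Idi1 (2.08 and 2.94) and Msmo1 (2.03 and 2.27) led. In NK cells, the granzyme genes Gzmg, Gzmf and Gzme were lower with PLX4720 in both genotypes, while of the 17 cytotoxic effector genes 6 were higher and 5 lower in both (median log2 -0.0018). In the whole sort, the complement genes C1qa, C1qb and C1qc and the protease gene Lgmn were higher in MSM-IL33ko than in MSM-IL33wt in both treatments, with C1qa at 1.16 (PLX4720) and 1.78 (untreated). The share of the class labelled Macrophage was 1.77 and 1.82 times as high there.

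Il33 transcripts did not test the knockout. No Il33 UMI was found in any ST2-sorted library of the Tx1 arm, where 0 of 57922391 UMIs in the deepest node library allows up to 0.0518 CPM. In the Tx7 arm the node libraries held 45 and 121 Il33 UMIs in MSM-IL33ko and 57 and 20 in MSM-IL33wt, treated and untreated. Il1rl1 ranged from 62.8 to 152.3 CPM in node libraries, from 155.3 to 355.4 in ST2-sorted tumour libraries and from 4.34 to 10.6 in CD45-sorted libraries.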

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

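Tests of exchanged labels, of the share of cycling cells and of other groupings of the libraries were chosen after the results were seen. So were counts thinned to the smallest library and counts without high Scrublet scores or cells over 10% mitochondrial counts. For exchanged labels, a bound by the spread of list members was added once the values were known. Without it, the cytotoxic list would also have counted against an exchange as the sole source. The test of abundant macrophage transcripts was repeated over all tested genes, with its bounds kept. Its first result, from a gene set limited to small p values, was found void. The effect of PLX4720 differed between genotypes for 1258 genes in node Treg cells, a difference between groups by a test of the interaction itself. As the sole source of the node proliferation difference, labels exchanged in the Tx1 arm are argued against by the Tx7 arm (median log2 difference -1.06 ± 0.46 SD of members). The Tx7 arm cannot show whether labels of the Tx1 arm were exchanged, and the SD of members does not measure spread between libraries. Exchanged labels as a sole source stay open for the cytotoxic list (-0.89 ± 1.84 SD in the Tx7 arm, -3.52 in the Tx1 arm). The same holds for the tumour proliferation list (-0.0077 in the Tx7 arm, -2.09 in the Tx1 arm). RNA or cells of the class labelled Cd8 cycling accounted for 6.07% of the level of the proliferation list in treated MSM-IL33wt libraries (median over members). For the cytotoxic list the median was 25.02% (35.1% in the Tx1 and 12.8% in the Tx7 arm, members from 0.348% to 674%). At least 50% was accounted for in 7 of 17 cytotoxic members in the Tx1 and 6 in the Tx7 arm. That source stays open for the cytotoxic genes. This test scored levels in treated MSM-IL33wt libraries and not the interaction itself. A share of cycling Treg cells that depends on genotype and treatment is a candidate explanation for part of the pattern. Its exact permutation p = 0.0286 in the node is the smallest possible (adjusted p = 0.114), with p = 0.0571 in the tumour (adjusted p = 0.229). The cycling subset and the proliferation list describe the same process, so this test is no separate evidence. The libraries make 13 distinct splits for this test, too few for a share under 0.05: 1 split gave as many genes, the real one with 1258, and the highest other gave 3.

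Genes higher in MSM-IL33ko Treg1 cells of the tumour were weighed against RNA from macrophages. Of the 20 most abundant transcripts of the moMacrophages class that were at least 8-fold above the Treg class, 20 were higher in MSM-IL33ko Treg1 cells and 8 passed the threshold, although Lyz2 and Cst3, named after their values were seen, differed by 0.17 and 0.32 on the log2 scale. Of the 92 genes that rose, 92.4% were at least 4-fold higher in moMacrophages than in Treg cells, against 4.94% of all 9729 genes tested. Macrophage RNA may therefore account for most of this difference, and the sort for ST2 would not remove free RNA. Of 20 splits, 2 gave as many genes as the real 93, and the highest other gave 115. The 93 ran from 11 (without treated MSM-IL33ko of the Tx7 arm) to 173 (without that of the Tx1 arm) leaving out 1 library, and were 16 with thinned counts.

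Y-linked transcripts were found in the MSM-IL33ko libraries of the Tx1 arm. Among their cells, 13.3% of the 976 with a Y-linked UMI also had an Xist UMI, against 83.8% of the 3223 without one, a ratio of 0.159. The libraries differed, and the contrast was weaker in the tumour. Of cells with a Y-linked UMI, 7.14% (treated) and 6.71% (untreated) had an Xist UMI in the node, against 30.7% and 23.1% in the tumour. Of cells without one, 79.6% to 86.8% had an Xist UMI in these libraries. Male and female cells mixed in these libraries may explain this, so sex and genotype are partly confounded in that arm.

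In node Treg1 cells the interaction called 103 genes (2 of 13 splits gave as many, highest other 344), among them Cd8a (log2 difference -5.09 ± 0.95 SE) and Cd8b1. That count was 20 without cells over 10% mitochondrial counts, 50 with DESeq2 and 172 with RLE size factors. Leaving out 1 library of the Tx1 arm gave 31 and 26 (untreated MSM-IL33ko and MSM-IL33wt), and leaving out any 1 of the Tx7 arm gave 214 to 265. In the node class labelled Cd4 the interaction called 8 genes (2 of 13 splits, highest other 148; 3 with DESeq2 and 14 to 164 leaving out any 1 library; 100 without the low-count filter), and the Tx7 effect differed from the Tx1 effect for 2 genes, Ccl1 and Csf2 (0 to 7 leaving out 1 library, 33 without the low-count filter). In the node class labelled Cd8 the interaction called 5 genes (12 of 13 splits, highest other 36; 0 with DESeq2 and 6 to 27 leaving out 1 library; 21 without the low-count filter), and the Tx7 effect differed from the Tx1 effect for 5 genes (0 with DESeq2 and in thinned counts, 5 to 22 leaving out 1 library, 17 without the low-count filter). Each of the libraries changed at least 1 of these 4 counts by over 1.5 times. The splits of the libraries for these interactions are too few for a share under 0.05. In the whole ST2 sort, the genotype effect differed between tissues for 2 genes, Klra2 and Cybb (1 of 58 splits, highest other 1). This count was 0 with RLE size factors and without the highest Scrublet scores, 47 without the low-count filter and 215 with DESeq2. Leaving out a pair of libraries gave 0 for 4 of the 8 pairs and 1 to 6 for the others.

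For genotype in the node, 3 of 20 splits gave as many genes as the real 2 in Treg cells (highest other 569), 7 of 20 as many as the real 2 in the Cd4 class (highest other 210) and 12 of 20 as many as the real 3 in the Cd8 class (highest other 29). The 20 splits are too few for a share under 0.05. The split with 569 genes set treated MSM-IL33wt with untreated MSM-IL33ko libraries, a structure of the samples that follows the interaction. For tissue, 1 of 58 splits, the real one, gave as many genes in Treg cells (8394, highest other 6196), Treg1 cells (2151, highest other 849) and the whole sort (6862, highest other 4001). These splits were drawn at random, did not keep the pairing of node and tumour, and were chosen after the results were seen. They rank the real split highest among those drawn and do not exclude chance. The Treg1 count was 1109 without cells over 10% mitochondrial counts.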

How the results depend on the processing

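The alternatives that left out cells with high Scrublet scores, cells with over 10% mitochondrial counts or a cycling subset, that left out both MSM-IL33ko libraries of the Tx1 arm, or that thinned counts were chosen after seeing the data. The tissue difference in Treg cells stayed within 1.5 times of its 8394 genes under every alternative run (7448 to 8095 leaving out a pair). The node Treg interaction gave 557 genes with DESeq2 and 244 without the cycling subset, against 1258, and 359 to 1673 leaving out a library, and stayed within 1.5 times with depth thinned to the smallest library. Node Treg counts moved with DESeq2 to 1 (genotype) and 11 (Tx7), without the low-count filter to 34 (genotype), 14 (Tx1), 68 (Tx7) and 26 (Tx7 minus Tx1), without the cycling subset to 4 (genotype) and 14 (Tx7), and without both MSM-IL33ko libraries of the Tx1 arm to 7 (genotype) and 57 (Tx7). Tumour Treg counts moved with DESeq2 to 1 (genotype), 4 (Tx1), 95 (Tx7), 10 (Tx7 minus Tx1) and 2 (interaction), without the low-count filter to 24, 32, 259, 21 and 171 in that order, without the cycling subset to 5 (Tx7) and 1 (Tx7 minus Tx1), with thinned counts to 1 (Tx7 minus Tx1), and without both MSM-IL33ko libraries of the Tx1 arm to 46 (genotype) and 677 (Tx7). The genotype by tissue count moved from 0 to 12 without the filter. Leaving out 1 library gave 0 to 6 (node genotype), 0 to 12 (node Tx7), 0 to 28 (tumour genotype), 0 to 69 (tumour Tx1), 0 to 88 (tumour Tx7), 0 to 4 (tumour Tx7 minus Tx1) and 8 to 142 genes (tumour interaction). The causes were not tested.

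Of 201 gene list calls, 7 held with an estimated correlation, all of them for tissue in Treg1 cells, and fry made 49 calls. The 4 genes past the size rule between genotypes in the CD45 sort became 7 without the cells of highest Scrublet score. The Treg share difference in the node, with a logit difference of -0.03 for genotype and 0.07 for treatment, changed sign leaving out 1 library, to 0.14 and 0.10 for genotype (range -0.19 to 0.14) and to -0.067 and -0.0486 for treatment (range -0.067 to 0.263). For moMacrophages in the node, treatment changed to 0.01999 (lowest -0.569) without the treated MSM-IL33ko library of the Tx1 arm. Over all classes, 44 of 320 share differences changed sign leaving out 1 library and 5 of 160 under other alternatives, and none passed the threshold. The smallest p that these permutations allow keeps 1 class alone from passing the correction. Of 2791 values of named genes leaving out 1 library, 2322 kept sign and side of the threshold, 462 lost the threshold and 7 changed sign; under other alternatives 233 of 2462 lost the threshold. AC171003.1 (2.54, with -3.32 and -3.39 without the treated libraries of the Tx7 arm, highest 4.35), Tulp2 (2.34, with -0.93 and -1.10 without its untreated libraries, highest 2.41) and Fos (1.16, with -0.0018 without treated MSM-IL33wt of the Tx1 arm, highest 2.52) in the node Treg interaction reversed, as did Xcl1 in the interaction of the node class labelled Cd8 (5.29, with -6.41 and -6.58 without the untreated libraries of the Tx7 arm, highest 7.86).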
